A study of Rattus norvegicus with 8 samples.

How the data were processed

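Total RNA of 8 samples of rat soleus muscle was measured on 8 single-channel expression arrays, 1 per sample. Per the labels' protocols, 3 µg of total RNA was reverse-transcribed with gene-specific primers and labelled with radioactive dATP. Per the labels, the RNA came from female Wistar rats aged 3 months. The array design, the image software, any background subtraction and any scaling by the authors are not given in the sources used here. The deposited table gives 1 linear spot intensity per feature and array, with 1185 features, no missing value and no value at or below 0. The deposited intensities were not on a common level between arrays, since the array medians spread over 2.24 on the log2 scale (4.74-fold from the lowest to the highest). Each array also had its own lower limit of signal, which remains in the values. The table holds no detection call and no background column, so whether a single feature was above background is unknown, and the number of arrays limits the precision.

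The features carry codes that start with R (702 features) or RG (483 features). The table does not pair these codes with genes, and 0 of the 1185 codes matched any identifier, symbol or synonym in a reference table of 47357 rat genes. No feature is therefore named as a gene or placed in the genome. The 26 lists of pathway and cell type genes fixed before the data were examined could not be tested, and the feature for FAK itself could not be found, so neither the plasmid's own transcript nor the labels could be checked. For the same reason at most 2 features per direction are given by their codes.

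Samples were grouped by their titles into FAK plasmid (n = 4) and empty plasmid (n = 4). The series design text describes a paired comparison of the 2 legs, so the pair was a block in the main model. The animal number stands in both titles for 3 pairs (423, 427-428 and 429-430). The title of 1 empty-plasmid sample has no number. It was set against FAK sample 422, which has no other partner, so pair 422 rests on elimination. What a double number such as 427-428 means is not given in the sources used here, so such a sample may hold RNA of more than 1 animal. The deviations of the 2 samples of a pair from their group means correlated across features with r = 0.24 in pair 422, 0.04 in pair 423, 0.49 in pair 427-428 and 0.39 in pair 429-430. These values also carry the difference between the kinds of title, and samples of 2 different pairs of the same kind gave 0.24 and 0.27 (1 number) and 0.28 and 0.33 (2 numbers), so they do not show the pairing of samples 422 and 423, which rests on the titles and the design text. Any 2 arrays had identical values at 0% of features, so none was a copy of another.

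The intensities were log2-transformed with no offset and quantile-normalized across the 8 arrays. This step had been set for tables whose medians spread over more than 0.2. Each feature was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, pair as block, two-sided), with Benjamini-Hochberg adjustment over all 1185 features and a threshold of adjusted p 0.05. Each array's lower limit of signal stays in the values. If it is background added to the signal, which could not be checked, log2 changes of dim features are understated. The features given by code were the 2 of smallest unadjusted p in each direction among those with unadjusted p under 0.05 and the same direction in all 4 pairs, since none passed the adjustment. The rule fixed beforehand allowed 10 per direction. A comparison of single values between the legs used an exact sign-flip permutation test, which with 4 pairs has 16 sign patterns and counts at least 2 of them, so it cannot reach a two-sided p of 0.05.

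The model was tested on simulated data drawn from the real features' means and spread, with 200 of 1185 features changed in each of 20 simulations. The noise of each of the 4 pairs was scaled to its observed spread by 1 factor for all features. The model recovered 65.4% of features changed by 0.5 on the log2 scale, 93.1% of those changed by 1 and 98.7% of those changed by 2, and 7.15% of its calls were false. The simulated noise was independent between features, which noise on real arrays need not be. It was also independent between pairs, whereas the real differences of pairs 422 and 423 were opposed (r = -0.28 across features). The real inequality of the pairs changed with brightness: the SD of differences was 0.74 in the brightest 20% and 0.18 in the dimmest 20% in pair 423, against 0.44 and 0.23 in pair 422. Recovery on the real arrays may therefore differ. These shares hold for 200 changed features. With few changed features the Benjamini-Hochberg adjustment asks for a smaller p, so recovery would be lower, and this was not simulated. The changes were also added in full to dim features, whose changes may be understated on the real arrays.

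The choices set before the data were examined were the grouping, the test, the rule for features given by code and these alternatives: no pairing, only the 3 labelled pairs, pairs as a random effect (statmod 1.5.0), median scaling, values as deposited, cyclic loess, an added offset of 3490 intensity units (the 10th percentile of all values), leaving out the dimmest 25% or 50% of features, leaving out each pair, a trended and robust eBayes, array quality weights and a threshold of 0.1. Background correction by normexp with an offset of 50, the pairs with 1 or with 2 animal numbers alone, and the array level as a covariate were added after seeing the data.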

Results

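The experiment asked whether extra focal adhesion kinase (FAK) changes gene expression in a slow muscle that no longer bears load. FAK is a tyrosine kinase at the sites where integrins couple cells to the extracellular matrix, and soleus is a postural muscle of the lower leg made mostly of slow fibres. A plasmid carrying FAK under the cytomegalovirus promoter was brought into 1 soleus of a rat by electric pulses, and the same plasmid without FAK into the soleus of the other leg. What the double animal numbers of 4 samples stand for is not given in the sources used here, so such a sample is not known to be a single muscle. From day 2 after the transfer the hindlimbs were unloaded by suspension for 7 days, after which the muscles were frozen and their RNA was hybridised to arrays of 1185 features. There were 4 samples with the FAK plasmid and 4 with the empty plasmid, in 4 pairs. No loaded muscle and no muscle without plasmid is among the samples, so the comparison is between plasmids within unloaded muscle.

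The arrays differed in signal strength. Among the empty-plasmid samples, the median intensity was 3294 in pair 422, 15600.5 in pair 423, 11423 in pair 427-428 and 10847.3 in pair 429-430. Among the FAK-plasmid samples it was 5020, 8232.3, 11471.4 and 11826.9 in the same order. The group means were 10291 ± 5123 (SD, n = 4) for the empty plasmid and 9138 ± 3186 (SD, n = 4) for FAK. FAK over empty, the median was 1.52-fold in pair 422, 0.528-fold in pair 423, 1.004-fold in pair 427-428 and 1.09-fold in pair 429-430. The mean log2 ratio of -0.05 ± 0.64 (SD, n = 4 pairs) did not differ from 0 (exact sign-flip permutation test, two-sided p = 1, where 2 of 16 sign patterns is the smallest share possible). Each array's 1st percentile served as an estimate of its lower limit of signal. The median feature stood 1.502-fold above it on the empty array of pair 422, 3.13-fold on the empty array of pair 423, and between 1.78-fold and 2.02-fold on the other 6 arrays. The share of features at more than 2 times the 1st percentile was 26.8% on the empty array of pair 422 and 69.5% on the empty array of pair 423, against 42.4% to 50.9% on the others.

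**Figure D1:**
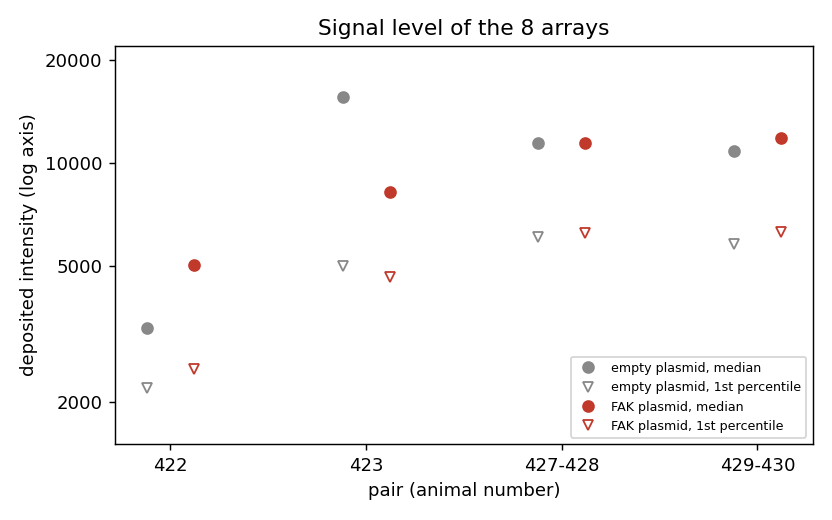
Median (filled circles) and 1st percentile (open triangles) of the deposited intensities of each array, on a log axis, by pair and plasmid. The arrays of pairs 427-428 and 429-430 lie close together, while the empty-plasmid array is the weaker one in pair 422, with a median of 3294, and the stronger one in pair 423, with a median of 15600.5.

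No transcript on the array was shown to differ between muscles with the FAK plasmid and muscles with the empty plasmid. Of 1185 features, 0 passed an adjusted p of 0.05 in the paired limma model, and the smallest adjusted p was 0.995. At an unadjusted p under 0.05 there were 19 features, 9 higher and 10 lower with FAK, where chance alone gives 59.3. This count depended on the processing and on single pairs: it was 71 with the array level as a covariate, 40 with array quality weights, 47 without pair 423, 5 after median scaling (5 higher, 0 lower) and 1 on values as deposited, with 0 features past the adjustment in each. The median size of a change was 0.07 on the log2 scale, and 0.15 after normexp background correction, an alternative added after seeing the data. The largest fitted change was a fall by 1.22 on the log2 scale, with a standard error of 0.75 and an unadjusted limma p of 0.159. It rested on a feature whose empty-plasmid values had an SD of 2.00 and which was higher with FAK in 1 of the 4 pairs.

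The intervals bound the size of change that these values leave possible. For 1155 features (97.5%) the 95% confidence interval of the paired model lay inside a 2-fold change in either direction, and for 1020 features (86.1%) inside a 1.5-fold change. The median half-width of the interval was 0.25 on the log2 scale. These bounds hold for the quantile-normalized values, in which the arrays' lower limits of signal remain. On the values as deposited, without normalization, 761 features had an interval inside 2-fold. After normexp background correction, 897 features (75.7%) had an interval inside 2-fold, the median half-width was 0.55, and again 0 features passed the adjustment, with 20 at an unadjusted limma p under 0.05.

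**Figure D2:**
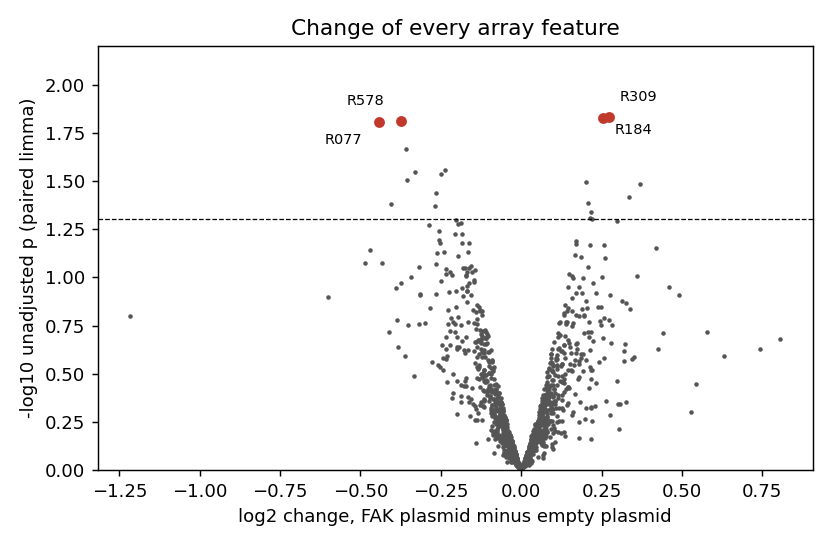
Log2 change of each of the 1185 features (x axis, FAK plasmid minus empty plasmid) against the -log10 of its unadjusted p in the paired limma model (y axis). The dashed line marks an unadjusted p of 0.05, above which lie 19 features, and the 4 red points are the features given by code.

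The features closest to a difference were R309 and R184, with higher values in FAK muscle, and R578 and R077, with lower values. None passed the adjustment (limma, adjusted p = 0.995 for each). R309 averaged 12.57 ± 0.10 on the log2 scale with FAK and 12.30 ± 0.09 with the empty plasmid (SD, n = 4 each), a difference of 0.27 with a standard error of 0.08. R309 was among the dimmest features, at the 11.9th percentile of mean signal, and its difference was 1.23 with a standard error of 0.24 after normexp background correction (adjusted p = 0.999). R184, at the 90.1th percentile, averaged 15.27 ± 0.49 with FAK and 15.01 ± 0.50 without (SD, n = 4 each), and its difference of 0.26 ranged over the pairs from 0.18 to 0.33. R578, at the 94.4th percentile, averaged 15.68 ± 0.41 with FAK and 16.06 ± 0.21 without, a difference of -0.37 with a standard error of 0.11. R077, at the 64.6th percentile, averaged 13.27 ± 0.31 with FAK and 13.71 ± 0.41 without. Its difference was -0.44 with a standard error of 0.13, and -0.72 after normexp correction (adjusted p = 0.999). Each of the 4 had the same direction in 4 of 4 pairs of the normalized values, as the rule for choosing them required. On values as deposited, R309 and R184 were lower with FAK in pair 423, and R578 and R077 were higher with FAK in pair 422.

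**Figure D3:**
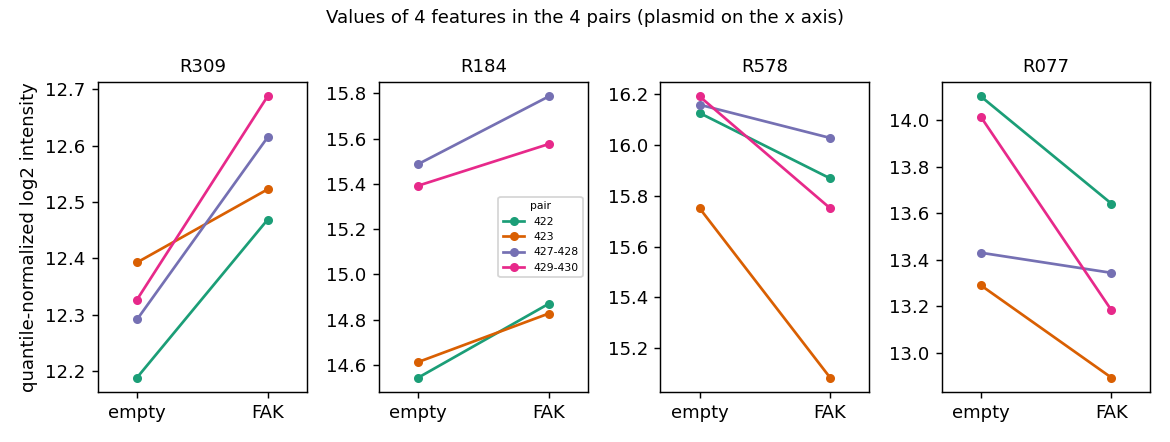
Quantile-normalized log2 intensity of R309, R184, R578 and R077 in the empty-plasmid and FAK-plasmid sample of each pair, with a line joining the 2 samples of a pair. The 4 lines run the same way in each panel, as the rule for choosing them required, over differences from 0.13 to 0.36 for R309 and from -0.83 to -0.09 for R077.

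The 4 pairs did not share a pattern of differences. Features with the same direction in all 4 pairs numbered 126 (10.6%), 50 higher and 76 lower with FAK, against 148 (12.5%) that independent directions would give. The count was 50 after median scaling and 17 on values as deposited. Across features, the within-pair differences of 2 pairs correlated with r from -0.28 (pairs 422 and 423) to 0.11 (pairs 422 and 427-428), with a mean of -0.08 over the 6 combinations. The corresponding rank correlations for these pairs were -0.31 and 0.15. Features are not independent replicates, so no p is given for these correlations.

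The pairs differed in precision. The SD of the within-pair log2 differences over all features was 0.37 in pair 422 and 0.46 in pair 423, whose titles give 1 animal number, against 0.16 in pair 427-428 and 0.23 in pair 429-430, whose titles give 2. Differences of more than 2-fold were seen at 29 features in pair 422 and 52 in pair 423, against 2 in pair 427-428 and 4 in pair 429-430. Per feature, the median SD of the 4 within-pair differences was 0.21, and the median SD between samples of 1 group was 0.19. These depended on the processing: they were 0.46 and 0.41 after normexp correction, 0.38 and 0.28 after median scaling, and 0.64 and 0.83 on values as deposited. A difference of 2 unrelated samples has an SD larger than that of 1 sample by the square root of 2 (1.41). That the first SD was the larger after normalization therefore does not mean that pairing widened the spread. It lay below 1.41 times the second, so differences within pairs were narrower than unrelated samples would give, but only slightly after median scaling. The 2 samples of a pair also share the kind of title, so this does not show that the pairing itself narrowed them.

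The plasmid comparison was repeated within each kind of title. In the 2 pairs with 1 animal number, 0 features passed the adjustment and 12 had an unadjusted limma p under 0.05, 2 higher and 10 lower with FAK. In the 2 pairs with 2 animal numbers, 0 features passed and 20 had an unadjusted p under 0.05, 13 higher and 7 lower. A limma test of the difference between the effects of the 2 kinds of pair gave 0 features past the adjustment and 18 at an unadjusted p under 0.05. Without pair 422, whose pairing rests on elimination, 0 features passed and 11 had an unadjusted limma p under 0.05. Without pair 423 these counts were 0 and 47, and without pair 429-430 they were 0 and 8. Each of these unadjusted counts lay below the 59.3 that chance alone gives over 1185 features, so no effect is read from their directions.

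**Figure D4:**
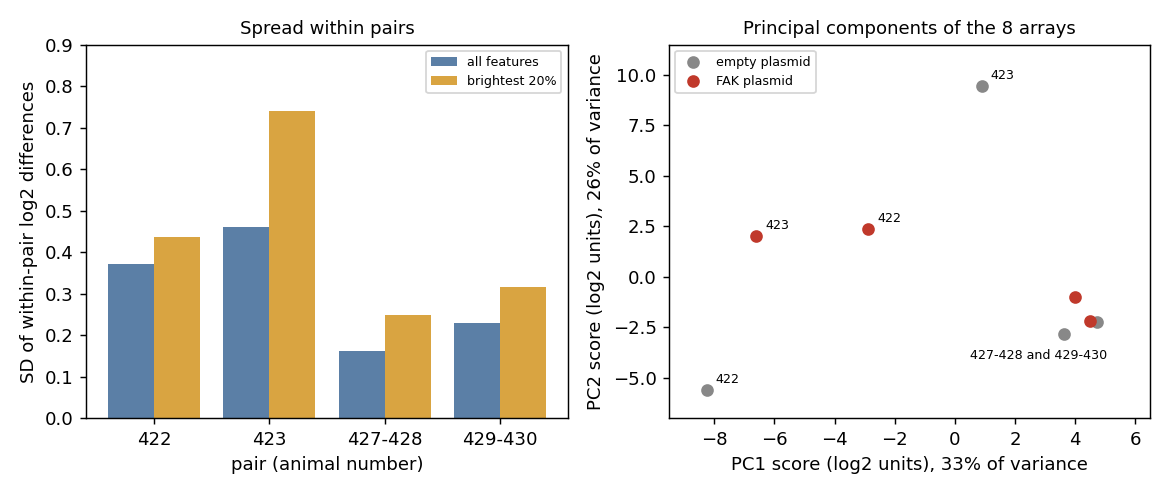
Left, SD of the within-pair log2 differences by pair, over all features (blue) and over the brightest 20% (237 features, yellow). Right, scores of the 8 arrays on the first principal components of the normalized values, in log2 units, where the 4 arrays of pairs 427-428 and 429-430 fall together at scores of 3.63 to 4.73 on the first and the FAK arrays do not separate from the empty-plasmid arrays.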

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

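All of the tests in this part were chosen after the results were seen, except that on the signal level of the arrays, which was set before its value was known. Of 19 groups of 4 values examined for a value far from the rest, 1 held one, about what chance gives at 1 in 20 groups. In that group, the normalized value of R578 was 15.75 in the empty-plasmid sample of pair 423 and 16.13, 16.16 and 16.19 in the other 3 empty-plasmid samples. The gap was 0.852 of the group's range, above the critical value for 4 values in Dixon's test.

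The samples with 1 and with 2 animal numbers in their titles stood further apart than the plasmid groups did. In limma fits without pairing, the split by kind of title gave 34 features past an adjusted p of 0.05, 13 higher and 21 lower in the samples with 1 number, against 0 for the plasmid and 0 as the highest of the other 34 splits into 4 and 4 samples. These fits count both samples of a pair as independent, and the count was 27 with the pair as a random effect and 2 with each pair averaged to 1 value. A single response curve per array (scale, lower limit or saturation common to all features) is argued against as the whole cause. Values as deposited, which leave all of such a curve in, gave 3 features. Median scaling, which takes out scale but leaves the rest in, gave 4 features. Quantile normalization, which takes out the whole curve, kept these 4 among its 34. The rise in count is no evidence by itself, since the median SD between samples of a plasmid group was 0.28 after median scaling and 0.19 after quantile normalization. Chance stays open: the split by kind of title is itself 1 of only 3 splits that keep pairs together, and 3 splits are too few for a share under 0.05. The others of these 3 gave 0 features. The sets of animals, their handling and the preparation of RNA or arrays coincide with the kind of title and were not tested.

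The wider differences within pairs 422 and 423 were another pattern. Over all features, the SD also rose with the mismatch in signal level between the 2 arrays of a pair. The log2 ratios of array medians were 0.006, 0.12, 0.61 and -0.92 in pairs 427-428, 429-430, 422 and 423, with SDs of 0.16, 0.23, 0.37 and 0.46. With 4 pairs, the kind of title and this mismatch cannot be told apart. In the brightest 20% of features the SD was 0.44 and 0.74 in pairs 422 and 423, against 0.25 and 0.32 in the others, a ratio of at least 1.38, but pairs 422 and 423 themselves differed there by 1.69-fold. In the dimmest 20% the SDs were lower in every pair (0.23, 0.18, 0.13 and 0.15, a ratio between the kinds of at least 1.19). This order speaks against weak signal near an array's lower limit. After normexp correction the dimmest features had higher SDs in every pair (1.12, 0.92, 0.70 and 0.81, against 0.51, 0.85, 0.30 and 0.36 in the brightest). The order therefore turns with the background. The height of the arrays above their lower limits does not decide it either. Pair 423, the widest, holds the array furthest above its limit (3.13-fold), but its FAK-plasmid array stood at 1.78-fold. The empty-plasmid array of pair 422 stood lowest, at 1.502-fold, so the 2 lowest arrays lie in the 2 widest pairs. Weak signal near the lower limit therefore stays open. If each double number stood for RNA averaged over 2 animals, SDs smaller by the square root of 2 (1.41) could follow. The observed ratios ran from 1.62 to 2.85, but pairs of the same kind differed by up to 1.41-fold themselves, so with 2 pairs of each kind this stays open.

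A further pattern was the opposed differences of pairs 422 and 423 (r = -0.28 across features). The empty-plasmid array was the weaker one in pair 422 and the stronger one in pair 423, and a candidate explanation is that differences follow the signal level of the 2 arrays even after quantile normalization. The slope of the within-pair differences on the log2 ratio of array medians had an unadjusted limma p under 0.05 at 297 features and passed the adjustment at 21, against 231 and 13 when the ratios of pairs 422 and 423 were exchanged (197 and 1 with those of the other 2 pairs exchanged as well), so it mostly restates the contrast between these 2 pairs. Of the 24 orders in which the 4 ratios can be assigned to the pairs, 2 gave as many by either count (the other, with 312 and 67, exchanges only pairs 427-428 and 429-430), so the test cannot exclude chance, and RNA quality or labelling that changes with signal level stays open. With this slope in the model, 0 features passed the adjustment for the plasmid.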

How the results depend on the processing

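The count of 0 features past an adjusted p of 0.05 was the same in all 20 alternatives, including a threshold of 0.1 (the 3 labelled pairs and leaving out pair 422 are the same fit, counted under both names). The mean differences of R309, R184, R578 and R077 kept their direction without passing the adjustment in every alternative that kept the feature (adjusted p 0.680 to 0.9999). Their unadjusted limma p ran from 0.11 to 0.36 after median scaling, and that of R184 was 0.40 with no replicate block. R309 was dropped when dim features were left out. The count at an unadjusted limma p under 0.05 (19, 9 higher and 10 lower) was 6 with no replicate block (2 higher, 4 lower), 14 with pairs as a random effect (2 higher, 12 lower) and 11 on the 3 labelled pairs (2 higher, 9 lower). It was 5 after median scaling (5 higher, 0 lower), 1 on values as deposited (1 higher, 0 lower), and 10 (2 higher, 8 lower) and 8 (2 higher, 6 lower) without the dimmest 25% and 50% of features. It was 40 with array quality weights (21 higher, 19 lower), 12 on the pairs with 1 animal number (2 higher, 10 lower) and 71 with the array level as a covariate (37 higher, 34 lower). Leaving out 1 pair gave 8 to 47. Intervals inside 2-fold fell from 1155 features to 761 on values as deposited, and to 568 without the dimmest 50%, where fewer features were tested. Features with the same direction in all 4 pairs (126) numbered 50 after median scaling, 17 on values as deposited and 66 without the dimmest 50%. The last of these follows from the fewer features. These counts were not recomputed with fewer pairs. The median SDs of the within-pair differences (0.21) and between samples of a group (0.19) were 0.38 and 0.28 after median scaling, 0.64 and 0.83 on values as deposited, 0.15 and 0.14 with the added offset, 0.25 and 0.24 without the dimmest 50%, 0.46 and 0.41 after normexp correction, and 0.11 and 0.11 on the pairs with 2 animal numbers. Leaving out 1 pair gave 0.151 to 0.219 and 0.147 to 0.203. The mean correlation of deviations within pairs (0.29) was -0.10 on the pairs with 1 animal number, 0.17 on those with 2, 0.13 after median scaling and on values as deposited, and 0.186 to 0.392 when 1 pair was left out. Values as deposited differ from median-scaled values only by a constant per array, so array level alone accounts for the changes between these settings. The log2 ratio of array medians was 0.61 in pair 422 and -0.92 in pair 423. For other changes the cause was not tested. The offset shrinks log2 differences by construction. The alternatives for the gene lists and the FAK transcript were not run, because no feature could be named. Signal over the lower limit of each array limits what dim features can show.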

Other observations

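The tests in this part were chosen after the results were seen. In the paired limma model, the real split gave 19 features with an unadjusted p under 0.05. Of the 8 splits that part all 4 pairs, 7 gave at least as many, counting the real split itself. The highest of the others, with the plasmids of pairs 423 and 429-430 exchanged, gave 103. With the plasmids of pair 423 alone exchanged the count was 77. That exchange makes the opposed differences of pairs 422 and 423 (r = -0.28 as labelled) run the same way. A higher count can follow from this and does not by itself show a wrong label. None of the 8 gave a feature past the adjustment, and 8 splits are too few for a share under 0.05. Because the feature that measures FAK could not be identified, the labels of these pairs were not checked. Without the pairing, all 35 of the 35 splits of the 8 samples into 4 and 4 gave at least as many features at an unadjusted p under 0.05 as the plasmid split, which gave 6, so chance is not excluded for that count. The highest other was the split by kind of title, with 249. These unpaired fits treat both samples of a pair as independent, which lowers the counts of splits that part the pairs and raises those of splits that keep them together. For features past the adjustment the 35 splits decide nothing, since the plasmid split gave 0 and every split reaches that. The highest other gave 34.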
